A study of Rattus norvegicus with 6 samples.

How the data were processed

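Polyadenylated RNA was measured by RNA sequencing in PC12 cells, a line derived from a rat adrenal pheochromocytoma that grows neurite-like processes in nerve growth factor (NGF). Per the labels' protocols, 500000 cells were seeded per 35 mm dish, and 24 h later they were moved to medium with 1% serum, 100 ng/ml NGF and 10 µg/ml magnetic nanoparticles. After 18 h in that medium 1 group was put into a toroidal magnet, and 9 h later both groups were frozen and their RNA was extracted. Stranded libraries were read as pairs of 75 bases. Groups and replicate numbers were taken from the sample titles, which gave 3 stretched and 3 control libraries. No label says whether replicates were separate cultures, so p-values and intervals measure only the spread between these samples, which may be technical.

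The submitters' processing notes list cutadapt 1.9 (adapter trimming), kallisto 0.43.0 (assignment of reads to transcripts without alignment) and DESeq2, and name the rn6 build. The transcript set and its release are not given in the sources used here. Per the file headers, each deposited table holds estimated counts, which the authors made with kallisto, beside TPM, an abundance corrected for length and scaled to a fixed total per library, the transcript length and its effective length. The estimated counts were not scaled between libraries, and the TPM values deposited by the authors sum to the same total in each library. Where a read matches several transcripts, kallisto divides it between them by expectation maximization, so that the estimated count of a transcript that shares reads need not be whole and carries an assignment error. No bootstrap estimates of that error were used here. Effective lengths gave the mean fragment length of each library as the transcript length minus the effective length plus 1.

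Rows are Ensembl rat transcript identifiers. The files do not pair them with genes, and the reference table used here (RefSeq genes of the GRCr8 assembly) holds no Ensembl identifiers, so 0 of 31202 identifiers matched a symbol. The planned sums per gene, the test of gene lists and a panel of named genes were therefore not run, nor was the planned correction for average transcript length, and the comparison was made per transcript, as the design allowed for this case. Transcripts are reported without gene names, positions or annotations. The rule for named items was the 10 transcripts with the smallest p where fewer than 10 passed the threshold. Identifiers are printed for the 3 of them that passed, and the rest are summarised. The identifier of 1 further transcript, the one with the smallest p among whole-count transcripts, is printed in the closing section and was chosen after its values were seen.

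Estimated counts were rounded to whole numbers. The main test was the quasi-likelihood test of edgeR 4.0.16 (glmQLFit with robust shrinkage, glmQLFTest) in R 4.3.3, stretched against control, with TMM normalization, the default filterByExpr filter and a Benjamini-Hochberg adjusted p under 0.05. Standard errors and 95% intervals of log2 fold changes were recovered from the fold change and F. Distances between libraries were Euclidean on log2 CPM with a prior count of 2, and the difference between groups was tested by exact permutation over the 10 splits of the 6 libraries into 3 and 3. Single values per library were compared by two-sided exact permutation tests, for which 0.1 is the smallest p that 3 against 3 can give. The comparisons of single values per library were not among the planned results. The other choices were fixed before the data were examined. So were the alternatives in DESeq2 1.42.0, limma 3.58.1, normalization, filter, unit, replicate block and left-out libraries. After the data were seen, the test was also run on whole-count transcripts alone, defined as those whose estimated counts lay within 0.01 of a whole number in all 6 libraries. All others are called shared-read transcripts. DESeq2 was run with its own filter and, as a setting added later, on the transcripts edgeR tested. A whole count does not prove that no read was shared, since the algorithm can also give all shared reads to 1 transcript.

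The test was tested on simulated data with the real means, library sizes and dispersions of the 16837 tested transcripts, of which 200 were changed. edgeR recovered 17 of 50 changed 1.25-fold, 30 of 50 changed 1.5-fold, 36 of 50 changed 2-fold and 46 of 50 changed 4-fold, with 18 calls among 16637 unchanged transcripts. On the same data DESeq2 recovered 18, 31, 37 and 46 with 44 calls among the unchanged ones, and limma-voom recovered 14, 29, 35 and 45 with 14; the simulation used dispersions estimated by edgeR. In this simulation of all transcripts, false calls were a larger share of each tool's calls than the adjusted p threshold aims for. That share was largest in DESeq2. The calls over all transcripts reported below may therefore hold more false ones than the threshold implies. The 95% intervals of edgeR held the true value for 95.4% of transcripts. With the 6868 whole-count transcripts, edgeR recovered 38 of 50 changed 1.25-fold and 50 of 50 changed 2-fold, with 11 calls among 6668 unchanged ones, where DESeq2 made 5 and limma-voom 12. The simulation held no assignment error beyond the dispersions. Recovery under an adjusted p depends on how many transcripts change, and only sets of 200 changed by at most 4-fold were tried. It may be lower where fewer transcripts change, and transcripts absent from one group were not simulated. Total estimated counts ran from 26026718 to 31186017 per library. On whole-count transcripts with at least 20 counts in a pair, libraries of the same group differed by 2.18 to 3.77 times the chi-square expected from counting alone, so none was treated as a duplicate.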

Results

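The series asks whether pulling on growing PC12 cells with a magnet changes their messenger RNA. Both groups were differentiated with NGF and carried magnetic nanoparticles, so NGF and the particles were common to both groups. Only the stretched group stood in the magnet. No group stood in the magnet without particles, so a pull on the cells cannot be told apart from exposure to the magnet itself. Below, a change with stretch means a difference between these groups. There were 3 stretched and 3 control libraries. Total estimated counts averaged 28327575 ± 2501741 (SD, n = 3) in stretched and 27296268 ± 1397958 (SD, n = 3) in control libraries, which did not differ beyond their spread (two-sided exact permutation p = 0.6). Of 31202 listed transcripts, 23528 had reads in at least 1 library, and 16837 passed the filter on low counts. These held 99.9% of the counts in each library.

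Few transcripts passed the test for a change with stretch. Of the 16837 tested, 1 rose and 2 fell at an adjusted p under 0.05 in edgeR's quasi-likelihood test, and 1290 (7.66%) had an unadjusted p under 0.05. All 3 were of low abundance, between 1 and 10 CPM on average, and each was near 0 in all libraries of one group. edgeR called 0 of the 8201 transcripts between 10 and 100 CPM, of which 715 had an unadjusted p under 0.05, and limma-voom called 0 and DESeq2, with its own filter, 54 of them. Of the 2305 above 100 CPM, edgeR called 0, with 159 at an unadjusted p under 0.05, limma-voom 0 and DESeq2 10. In 2358 transcripts (14.0%) the 3 stretched libraries did not overlap the 3 control libraries, against 10% that chance gives on average over splits of the libraries, with 1286 higher and 1072 lower in stretched cells. A split that mixed the groups gave more, 2412, so the excess over 10% cannot be put down to stretch.

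**Figure D1:**
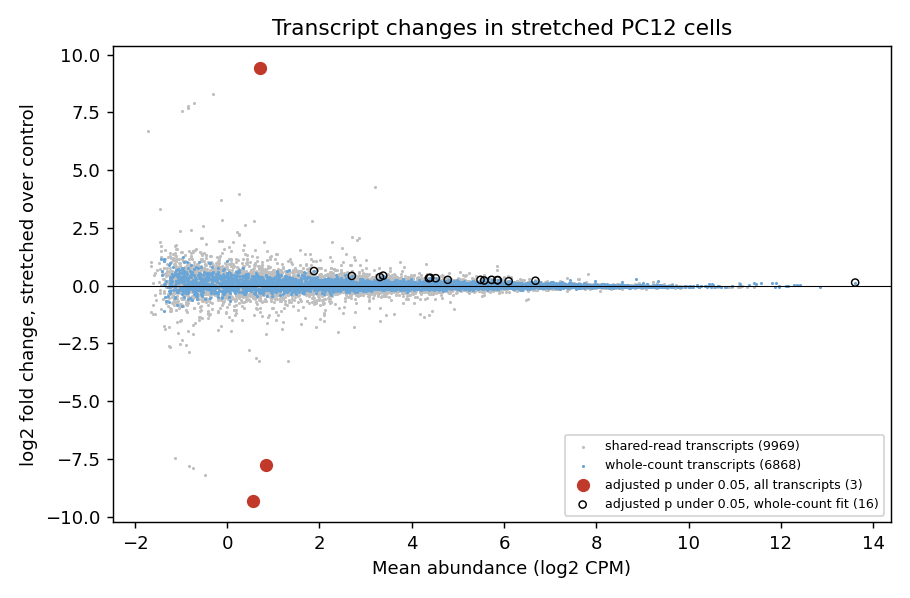
Each point is 1 of the 16837 tested transcripts, with mean abundance (log2 CPM) on the x axis and the fitted log2 fold change of stretched over control on the y axis; grey points are shared-read and blue points whole-count transcripts. The 3 transcripts past the threshold (red) lie at low abundance and far from 0, while the 16 called among whole-count transcripts alone (open circles) lie close to the 0 line.

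The transcript with the smallest p, ENSRNOT00000066419 (666 bases), fell. It had 77.1 ± 5.1 estimated counts (SD, n = 3) in control libraries and 0 in each stretched library. Against a floor of 3 counts per library this was at least 26.9-fold lower in stretched cells, with an adjusted p of 0.0145 in edgeR. ENSRNOT00000018934 (1194 bases) also fell, from 95.5 ± 35.1 to 0.19 ± 0.328 estimated counts (SD, n = 3), with an adjusted p of 0.0146 in edgeR and 0.0615 in limma-voom, which did not call it. Its rounded counts were 287 in the control libraries together and 1 in the stretched ones, a ratio of 299.7 with an exact 95% interval from 53.4 to 11880 that covers counting error only and is not on the scale of the floor used for the other 2. The 1 rounded count came from a fractional estimate of 0.57 in stretched replicate 1. ENSRNOT00000090673 (1926 bases) rose to 88.0 ± 18.4 estimated counts (SD, n = 3) in stretched libraries from rounded counts of 0 in each control library. It was at least 28.3-fold higher against the same floor, with an edgeR adjusted p of 0.0152. The estimated counts of all 3 were fractional, so these transcripts share reads with others, and the fit carries no term for that assignment error. The number called changed when 1 library was left out: edgeR called 0 transcripts without control replicate 2, with 981 at an unadjusted p under 0.05, 1 without stretched replicate 1 or without stretched replicate 2, and 8 without control replicate 3. Over the 6 such fits, in which 1 group had 2 libraries, ENSRNOT00000066419 passed in 4, ENSRNOT00000018934 in 2 and ENSRNOT00000090673 in 1.

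**Figure D2:**
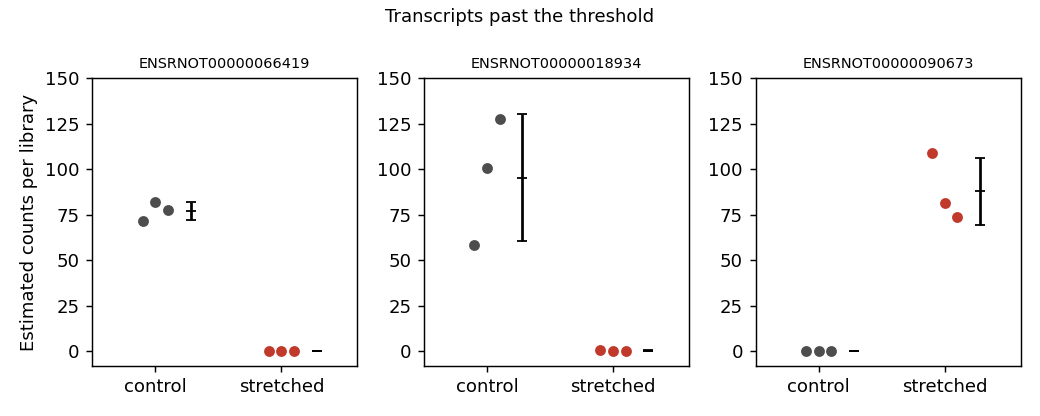
Estimated counts per library (y axis) in control and stretched cells (x axis) for the 3 transcripts past the threshold; dots are libraries and the bar beside them is the mean ± SD of 3. In each transcript 1 group lies at or near 0 and the other between 58.1 and 127.7 counts.

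The 7 next transcripts by p did not pass in edgeR, with adjusted p from 0.0667 to 0.232, but DESeq2 called all 7 (adjusted p from 5.54e-05 to 0.00326) and limma-voom 5 of them. Among the 10 with the smallest p, 6 were higher and 4 lower in stretched cells, and 8 were close to 0 in all libraries of one group and at 5 or more counts in each library of the other. All 10 were shared-read transcripts, against 59.2% of the tested ones. All 10 also averaged under 10 CPM, where that share was higher, with 69.3% between 1 and 10 CPM and 70.9% below 1 CPM. The DESeq2 Wald test, the tool the submitters' notes name, tested 20533 transcripts under its own filter and called 108 with 74 higher and 34 lower, including the 3 above; 99 of the 108 were shared-read transcripts and 61 had a fitted change under 1.5-fold. On the transcripts edgeR tested, DESeq2 called 36, of which 23 were higher, a setting added after the data were seen. limma-voom, on the same 16837 transcripts as edgeR, called 8, of which 5 were higher. When the 6868 whole-count transcripts were tested alone, a choice made after the data were seen, edgeR called 16, all higher in stretched cells by 1.10-fold to 1.55-fold, and DESeq2 called 0 of the same transcripts with 355 at an unadjusted p under 0.05. That edgeR count was 103 without control replicate 3, 25 without stretched replicate 1 and 1 without stretched replicate 3. It was 0 without stretched replicate 2, control replicate 1 or control replicate 2, with 486, 522 and 534 transcripts at an unadjusted p under 0.05.

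For most transcripts the intervals excluded a change of 1.5-fold or more between these samples, leaving aside the assignment error of shared reads. They rest on the spread between the libraries, which may be technical, so they may leave out a spread between cultures. The 95% interval of the fold change lay wholly within 1.5-fold either way for 12545 of the 16837 transcripts (74.5%) and within 2-fold for 87.6%. The median standard error of the log2 fold change was 0.077. Precision rose with abundance. Among transcripts above 100 CPM, 99.5% had intervals within 1.5-fold, and the median standard error was 0.035. Between 10 and 100 CPM the share was 96.3%, and between 1 and 10 CPM it was 50.0%. Below 1 CPM no interval of the 1631 transcripts fell within 1.5-fold and 28.8% fell within 2-fold. In all, 31 transcripts had intervals wholly beyond 1.5-fold (55 in limma-voom), 18 of them below 1 CPM and 13 between 1 and 10 CPM; these intervals are not adjusted for the number of transcripts. Shared-read transcripts were less precise, with 66.0% within 1.5-fold against 86.9% of whole-count transcripts. This comparison was not matched on abundance. Shared-read transcripts made up 70.9% of those below 1 CPM, 69.3% between 1 and 10 CPM and 49.3% above 100 CPM. The gap can therefore not be put down to shared reads alone. All 31 transcripts with intervals beyond 1.5-fold in edgeR were shared-read ones and 0 were whole-count ones. The intervals of these 31 therefore leave out an assignment error.

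The most abundant transcript (1545 bases) stood at 14392 ± 324 TPM (SD, n = 3) in stretched and 13122 ± 598 TPM (SD, n = 3) in control cells. The 10 most abundant together held 7.51 ± 0.121% of TPM (SD, n = 3) in stretched and 7.06 ± 0.262% (SD, n = 3) in control libraries. For both, every stretched library was above every control library, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 can give. Transcripts with at least 1 estimated count numbered 20370 ± 180 (SD, n = 3) in stretched and 20121 ± 138 (SD, n = 3) in control libraries (two-sided exact permutation p = 0.2). The mean fragment length was 173.8 ± 2.51 bases (SD, n = 3) in stretched and 169.3 ± 3.33 bases (SD, n = 3) in control libraries (two-sided exact permutation p = 0.3).

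Pearson correlations of log2 CPM across transcripts, which are not independent replicates, were 0.9757 to 0.9807 within groups and 0.9751 to 0.9802 between groups. The mean distance was 72.6 between and 70.8 within groups. The difference of 1.79 was exceeded by 1 of the other splits of the libraries, with 2.48 (one-sided exact permutation p = 0.2, where 0.1 is the smallest the 10 splits can give). The first principal component took 24.5% of the variance, and on it control replicate 3 (4.27) lay above stretched replicate 1 (-12.5) and below stretched replicates 2 (21.7) and 3 (35.6), with control replicates 1 (-29.7) and 2 (-19.3) at the other end.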

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

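Over all transcripts the number called, 3 in the main edgeR fit, stayed within 2 to 4 with limma-trend on log2(TPM + 0.1). It stayed in that range in edgeR under DESeq2 size factors, upper-quartile normalization, no filter, a stricter filter and no robust shrinkage. It was 108 with DESeq2 under its own filter, 36 with DESeq2 on the transcripts edgeR tested (added after the data were seen), 8 with limma-voom, 1 with limma-trend on log2(TPM + 1) and 6 with the latter unfiltered, and 0 to 8 when 1 library was left out. With the replicate number as a block it was 0, with 1671 transcripts at an unadjusted p under 0.05. Same-numbered libraries hardly deviated together (r of 0.087, 0.044 and 0.07), although every library correlated best with its own number; the labels do not say that a number marks a shared day, so this is only a hint. Over 155 values of the 10 transcripts with the smallest p under other settings, 0 reversed, 21 lost and 14 gained significance. ENSRNOT00000066419 passed in 14 of 17 settings, ENSRNOT00000018934 in 9 and ENSRNOT00000090673 in 7, with adjusted p up to 0.184 in each. The count of 16 over whole-count transcripts, and all settings on it, were chosen after the data were seen. It was 12 with limma-voom, 16 with DESeq2 size factors, 15 with a length trend removed per library, 14 with a tolerance of 0.001, 7 with upper-quartile normalization, 7 with the stricter filter, 79 (69 higher) without a filter and 146 (113 higher, 33 lower) with the replicate block, where the same-numbered r were 0.19, 0.094 and 0.12. It was 0 with DESeq2 under its own filter, with 316 at an unadjusted p under 0.05, and 0 on the transcripts edgeR tested, with 355, and 0 to 103 when 1 library was left out. The share of transcripts with intervals within 1.5-fold, 74.5% in the main fit, was 75.2% with limma-voom, 54.1% without a filter, 82.4% with the stricter filter, 70.1% to 71.0% with 1 library left out, 74.4% with the replicate block and 89.8% over whole-count transcripts. The distance between groups kept its sign in all 10 alternatives, from 0.319 to 2.88. The cause of these differences was not tested, except that filters change which transcripts enter and left-out libraries reduce n. Below 1 CPM, where counts are lowest, 0 of 1631 intervals lay within 1.5-fold; depth, spread and shared reads were not separated there.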

Other observations

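The fit over whole-count transcripts with its settings and every test of an explanation in this part, that of normalization included, were chosen after the results were seen; the edgeR and DESeq2 fits over all transcripts were planned. Among the 6868 whole-count transcripts alone, edgeR called 16, and all 16 were higher in stretched cells. Their fold changes were small, from 1.10 to 1.55 with a median of 1.19, and adjusted p ran from 0.0156 to 0.0426. The leading one, ENSRNOT00000046552 (2481 bases), rose from 35.7 ± 2.99 to 45.2 ± 2.61 CPM of whole-count reads (SD, n = 3), a log2 fold change of 0.34 ± 0.064 (SE) with an edgeR adjusted p of 0.0156. The most abundant transcript of the dataset was among them, with a log2 fold change of 0.14 ± 0.031 (SE). In the fit over all transcripts the same 16 had adjusted p from 0.452 to 0.589, with nearly the same fold changes and a median standard error of 0.065 against 0.0559; DESeq2 over all transcripts, under its own filter, called 5 of the 16. The common coefficient of variation between libraries was 3.10% over whole-count and 9.46% over all tested transcripts, and the prior degrees of freedom were 30.6 and 4.22.

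These 16 are a hypothesis of a small rise with stretch. limma-voom called 12 whole-count transcripts, 9 of them shared with the 16, and DESeq2 called 0 of the 6868 with 355 at an unadjusted p under 0.05. The choice among 3 normalizations is argued against as the source of the fold changes. They moved the groups apart by at most 0.0034 on the log2 scale, below the smallest called change of 0.137. A bias common to all 3 would not show in this comparison, and upper-quartile normalization left 7 of the 16 calls. Library depth cannot be told apart from an effect. The split of the 3 deepest from the 3 shallowest libraries gave 0 calls but 735 unadjusted p under 0.05, more than the 647 of the real split. Its cut fell between stretched replicate 3 (27259861 counts) and control replicate 1 (27067639 counts). The same split parts the libraries by sign on the first principal component, so it cannot single out depth. The 10 splits are too few for a share under 0.05; the real one gave 16 calls, as large in 1 split, and the highest other gave 0. Calls in the other direction appeared without a filter (10 of 79 lower) and without stretched replicate 1 (6 of 25 lower). The count changed with each library left out: it was 0 without stretched replicate 2, control replicate 1 or control replicate 2, 1 without stretched replicate 3, 25 without stretched replicate 1 and 103 (8 lower) without control replicate 3, in which the 16 lay a median of -0.011 from their mean against -0.192 and -0.197 in the other control libraries.

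Transcripts that were present in one group and absent in the other may come from the assignment of shared reads. In all, 24 transcripts were below 1 estimated count in all libraries of one group and at 5 or more in each library of the other, 16 of them present in stretched cells, and the 3 called by edgeR were among them. Shared reads fit this pattern: 23 of the 24 (95.8%) were shared-read transcripts, against 69.3% of transcripts matched on mean count (permutation p = 0.0023 over 10000 draws). The draws treat transcripts as independent, which those that share reads are not, so this p does not measure a spread between samples. A switch of isoforms with stretch stays open. The 10 splits cannot give a share under 0.05; as many on/off transcripts arose in 2 splits, with 24 in the real one and 28 in the highest other, and for edgeR's calls over all transcripts the real split was as large in 1, with 3 calls against 2. The split of the 3 deepest from the 3 shallowest libraries came close to it or passed it in other counts, with 1275 edgeR transcripts at an unadjusted p under 0.05 against 1290, and 2412 transcripts without overlap against 2358, so the excess of such transcripts over 10% cannot be put down to stretch.

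The 108 calls of DESeq2 under its own filter may come in part from the same source. A switch of isoforms with stretch stays open here too, since the share of shared-read transcripts cannot tell it from assignment error. Shared-read transcripts made up 91.7% of the 108 calls and 58.7% of the transcripts DESeq2 tested (Fisher's exact test, p = 2.79e-14). These shares were not matched on abundance. Transcripts that share reads are not independent of each other, and all rest on the same libraries. The p of this test therefore does not measure a spread between samples. Of the 108, 20 were of the on/off kind. Library depth stays open. DESeq2 called 144 when the 3 deepest libraries (stretched replicates 2 and 3 and control replicate 3) were set against the 3 shallowest. Totals lie close together at that cut, and the split also parts the libraries by sign on the first principal component. It therefore cannot single out depth. As many calls arose in 2 of the 10 splits, the real one included, and 10 splits cannot give a share under 0.05.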
